A study of Homo sapiens with 6 samples.

How the data were processed

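Total RNA from 293T cells was sequenced in 6 libraries, 2 for each of 3 groups: control, MLL2 knockout by CRISPR/Cas9 and PRMT1 knockdown by short hairpin RNA. The labels describe the libraries of a group as biological replicates, and they give no batch. The labels name TRIzol extraction and the TruSeq Stranded Total RNA Gold kit. The deposited files hold raw counts of reads per gene, 1 file per library, made by the authors with featureCounts. Per the submitters' notes, reads were checked with FastQC 0.11.4, trimmed with Trim Galore 0.6.10, aligned to hg38 with STAR 2.7.5a and counted with featureCounts 1.5.0-p1, with DESeq2 1.36.0 for the submitters' own tests. Per the file headers, the counting program was featureCounts 2.0.1 with the GENCODE 34 annotation, a minimum mapping quality of 10, paired reads and reverse-stranded counting (setting 2). The 2 sources differ in the featureCounts version, and which of them applies is not known. In the headers the alignments are named with WTshNT for the control libraries, MKshNT for the knockout and WTshPR for the knockdown. The labels do not explain these names, so whether the control and knockout cells also carried a hairpin, such as a non-targeting one, is not known. Reads that map to several near-identical copies, as for some histone, ribosomal protein and clustered protocadherin genes, score low in mapping quality, so the counts of those genes hold the reads that could be placed.

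Each file held 60669 genes, and the libraries summed to 20614522 and 20925045 counts (control), 22351532 and 20795206 (MLL2 knockout), and 20061471 and 21180838 (PRMT1 knockdown). Gene names were available for 60370 genes, and biotype and GC content came from GENCODE 29, the release at hand, which covers 58482 of them. The floor used for a group with no count is 3 counts in a library, averaged in CPM over the 2 libraries of the group. At this depth it is 0.138 to 0.149 CPM. Bounds written as "at least" set such a group at that floor. Where a group had 1 to 3 counts in total, a ratio of counts is given with its exact binomial interval. Both cover counting error only.

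Genes were kept by edgeR's filterByExpr with the groups, leaving 17575 genes, of which 13328 were protein-coding. Libraries were scaled by TMM and fitted together in edgeR 4.0.16 (glmQLFit, glmQLFTest) under R 4.3.3, with a term per group and 3 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 3 contrasts were each depletion against control and the knockdown against the knockout. Overlaps of calls were set beside the overlap of independent lists. Their fold changes were set beside 50 simulated pairs of unchanged groups with shared simulated controls, all 6 libraries being drawn from the control means.

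Before the data were examined, 48 gene lists with 1437 genes were written from textbook knowledge, with 1 gene not found in the files. The 45 lists with at least 5 tested genes were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and adjustment over the lists of a comparison, beside camera with an estimated correlation and fry. With the estimated correlation 0 lists were called in each comparison by camera, and 5, 5 and 1 lists had an unadjusted p under 0.05, while fry called 14, 28 and 18 (knockout, knockdown, and knockdown against knockout). Also fixed before the data were examined were the comparisons, the tests, the thresholds, the first set of alternatives and the rule for named genes. That rule takes the targeted genes, up to 10 protein-coding genes per direction and depletion with the largest change (5 for the knockdown against the knockout), at least 1 CPM in the higher group and both libraries on the same side of both libraries of the other group, up to 10 per direction shared by both depletions, and up to 4 members per list with the smallest adjusted p. The text prints part of these, and some genes that the rule takes are not reported here.

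The edgeR calls were tested on simulated data with the depth and spread of these libraries. Changed genes were drawn from those with an average log2 CPM above 2, and genes varied independently, so the recovered shares do not cover weakly expressed genes. For the knockout, 70.1% of genes with a true change of 1.5-fold, 92.5% at 2-fold and 100% at 4-fold were recovered, for the knockdown 61.2%, 95.5% and 100%, and for the knockdown against the knockout 67.2%, 91.0% and 98.5%. Of 17375 unchanged genes, 7, 9 and 9 were called. In simulated lists camera called the moved list and 1 of 44 others. A simulated chromosome shift of -0.5 was estimated at -0.51.

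The alternatives fixed beforehand included scaling by relative log expression, the Wald test of DESeq2 1.42.0, other count filters, protein-coding genes alone, fits of the compared groups alone and leaving out each library. Alternatives chosen after seeing the data were a correction for GC content and exon length (spline offsets per library, 17350 genes with a GC value), leaving out chromosomes 6 and 8, leaving PRMT1 out of the list of arginine methyltransferases, and setting each depletion against a different control library (2 residual degrees of freedom). The offsets of the GC and length correction hold a constant per library, so they also move the scaling between libraries. Medians and counts by window, chromosome stretch and exon length used genes with an average log2 CPM above 2. Windows were of 10 Mb with at least 10 such genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. No sequence reads were used.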

Results

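The libraries came from 293T cells, a transformed human embryonic kidney line, in 3 groups: control cells, cells with an MLL2 knockout made with CRISPR/Cas9, and cells with a PRMT1 knockdown made with a short hairpin RNA. The labels do not state whether the control and knockout cells also carried a hairpin. PRMT1 is an arginine methyltransferase, and MLL2 is a histone H3 lysine 4 methyltransferase. The name MLL2 has been used for both KMT2B and KMT2D, so both genes are given. The libraries held 20061471 to 22351532 counts in genes, and 17575 genes passed the count filter. Every fold change rests on n = 2 libraries per group, which the labels call biological replicates. The p-values measure the spread between these samples, pooled over all 3 groups and drawn towards that of other genes. The labels do not state whether the knockout libraries came from a single clone. If they did, traits of that clone could not be told apart from effects of the knockout. Fold changes of single genes are log2 values ± SE, and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. Coordinates are those of the files, on hg38 per the submitters' notes.

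PRMT1 (chromosome 19, 49675786 to 49689029) fell in the knockdown, from 306 and 319 CPM (counts scaled to the library total times its TMM factor) in the control libraries to 38.2 and 34.9 CPM. That was 8.56-fold lower (-3.10 ± 0.09, adjusted p = 5.5e-16). In the MLL2 knockout PRMT1 was higher, at 406 and 425 CPM (0.41 ± 0.08, adjusted p = 8.9e-04). KMT2B (chromosome 19, 35717973 to 35738878) was at 7.12 and 7.36 CPM in the knockout and 6.74 and 7.53 CPM in the control libraries (0.02 ± 0.25, adjusted p = 0.966). KMT2D (chromosome 12, 49018975 to 49059774) was at 20.8 and 24.2 CPM in the knockout and 22.5 and 17.03 CPM in the control libraries (0.19 ± 0.26, adjusted p = 0.661), with log2 changes from 0.00304 without control replicate 2 to 0.40 without control replicate 1. A frameshift or a small deletion need not lower a messenger RNA, so neither value checks the knockout label. In the PRMT1 knockdown both MLL2 genes were higher. KMT2B stood at 13.4 and 26.7 CPM (1.49 ± 0.24, adjusted p = 3.1e-05) and KMT2D at 37.8 and 95.5 CPM (1.76 ± 0.25, adjusted p = 8.4e-06). Without PRMT1 knockdown replicate 2 these log2 changes were 0.91 for KMT2B and 0.94 for KMT2D.

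**Figure D1:**
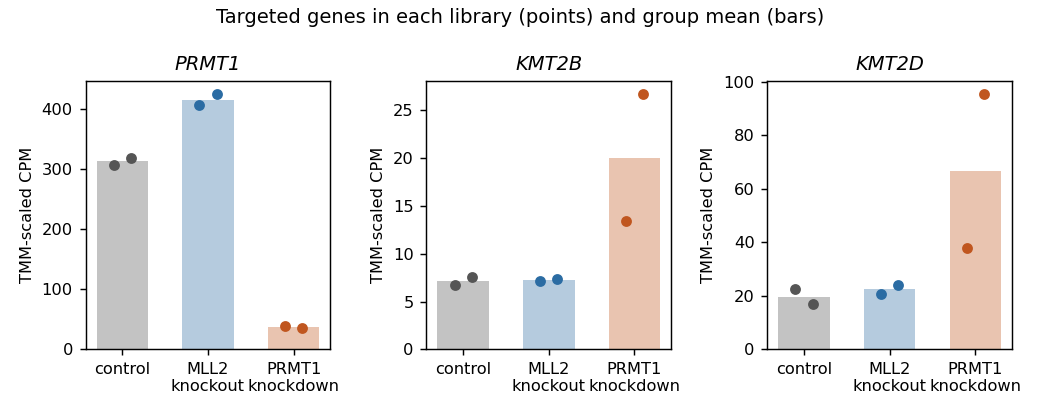
PRMT1, KMT2B and KMT2D in each library, in CPM, with group means as bars. PRMT1 fell to 38.2 and 34.9 CPM in the knockdown, while KMT2D reached 95.5 CPM in 1 of the 2 knockdown libraries.

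In the MLL2 knockout, several genes read in the control libraries had no count at all. PKP3, a desmosome protein, was at least 28.8-fold lower than in the control libraries, BEX1 at least 23.6-fold lower, and GATA5, a zinc finger transcription factor, at least 14.02-fold lower, with 3 counts per library as the floor, which covers counting error only. SLC7A3, a cationic amino acid transporter on chromosome X (70925579 to 70931125), fell by 6.96 ± 0.38 on the log2 scale (adjusted p = 6.3e-11), or fell by 6.16 without MLL2 knockout replicate 1 and fell by 8.68 without MLL2 knockout replicate 2. MAL2 was at least 8.84-fold lower and lies on the long arm of chromosome 8, where most genes were lower in the knockout. Other genes were higher. The phosphodiesterase gene PDE3A (2.63 ± 0.30), the cadherin gene CDH7 (2.03 ± 0.29) and TMEFF2 (3.33 ± 0.68) were higher. Of the 17575 genes tested, 3941 were called, 1817 higher and 2124 lower. At a change of at least 2-fold, 124 were higher and 790 lower. The balance of directions turned with DESeq2 (1791 higher, 1648 lower), relative log expression (2054 and 2044) and the GC and length correction (2501 and 2194). A fit of the control and knockout libraries alone, without the spread of the knockdown libraries, called 5386 genes. The count of 3941 was 2157 without control replicate 1, 1908 without control replicate 2, 2184 without MLL2 knockout replicate 1 and 2255 without MLL2 knockout replicate 2.

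Genes of the amino acid response, which the transcription factor ATF4 drives, were the most uniform group in the knockout: 34 of 38 were lower and 0 higher (34 lower adjusted over the list alone), with a median log2 change of -0.77. PCK2, which makes phosphoenolpyruvate in mitochondria, fell by 2.29 ± 0.11, ALDH1L2, a mitochondrial folate enzyme, fell by 1.42 ± 0.12, and DDIT4, an inhibitor of mTORC1, fell by 1.35 ± 0.09. Matrix genes were lower too, and since the study is known to have looked at matrix and adhesion genes in these libraries, their lists are not independent evidence of a direction. Of 42 laminins and matrix glycoproteins, 19 were lower and 1 higher (21 and 1 adjusted over the list alone; median -0.57), among them LAMA1 (-1.77 ± 0.11), SPARC (-1.36 ± 0.14) and FN1, fibronectin (-0.71 ± 0.09). Of 29 collagens, 16 were lower and 0 higher (16 lower adjusted over the list alone; median -0.68), with COL6A2 (-1.81 ± 0.15) and COL2A1 (-1.23 ± 0.11). Of 38 matrix remodelling enzymes and inhibitors, 18 were lower and 0 higher (18 lower adjusted over the list alone), with the lysyl oxidase genes LOXL1 (-2.92 ± 0.44) and LOXL4 (-2.81 ± 0.39). That list's median was -0.52, or -0.43 with the gene at 0 counts set to its bound. Of 15 epithelial markers, 7 were lower and 1 higher (9 and 1 adjusted over the list alone; median -1.38), with keratin 8, KRT8 (-2.42 ± 0.17), and the splicing factor ESRP2 (-3.65 ± 0.47). The camera test, which sets a list against all other genes with a preset correlation of 0.01, gave adjusted p = 1.1e-43 for the amino acid response, 1.2e-10 for laminins, 1.8e-07 for collagens, 2.0e-05 for remodelling enzymes and 1.7e-06 for epithelial markers. None of these calls held: adjusted p = 0.142 with an estimated correlation for all but collagens, and adjusted p = 0.408 with an estimated correlation for collagens. Here and for the lists below, the estimate rests on 3 residual degrees of freedom, so a lost call does not show that a list was unchanged.

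Other groups were lower in the knockout as well. Of 32 genes of hypoxia and glycolysis, 12 were lower and 0 higher (13 lower adjusted over the list alone; median -0.23). They included the glucose transporter SLC2A3 (-2.78 ± 0.22), the phosphofructokinase PFKP (-1.02 ± 0.09), and NDRG1 (-0.99 ± 0.09), which lies on chromosome 8 at 133 Mb among lower neighbours. Of 78 cytosolic ribosomal proteins, 20 were lower and 0 higher (22 lower adjusted over the list alone; median -0.16). RPL8 (-0.73 ± 0.08), RPS20 (-0.71 ± 0.09) and RPL30 (-0.69 ± 0.09) lie on the same arm of chromosome 8, and RPL3 (-0.65 ± 0.08) on chromosome 22. Of 46 replication-dependent histones, 22 were lower and 1 higher (23 and 1 adjusted over the list alone; median -0.25, and -0.25 with the gene at 0 counts set to its bound), with the linker histone H1-4 (-0.61 ± 0.09) and H3C10 (-0.52 ± 0.08). Of 29 p53 targets, 12 were lower and 3 higher (12 and 4 adjusted over the list alone; median -0.22), with EDA2R (-3.17 ± 0.39) and the DNA damage gene DDB2 (-1.02 ± 0.15), which lies on chromosome 11 at 47.2 Mb in a window of lower genes. Of 5 measured pluripotency markers, 3 were lower (3 adjusted over the list alone; median -0.58): TERT (-2.08 ± 0.32), DNMT3B (-0.59 ± 0.11) and LIN28B (-0.57 ± 0.09), the last on chromosome 6 at 105 Mb, also among lower neighbours. Camera's adjusted p was 1.5e-06 for hypoxia, 5.0e-07 for ribosomal proteins, 5.8e-06 for histones, 0.0308 for p53 targets and 0.0166 for pluripotency markers. None held: adjusted p = 0.408 with an estimated correlation for hypoxia and pluripotency markers, 0.706 for ribosomal proteins, 0.691 for histones and 0.662 for p53 targets. Without chromosomes 6 and 8 the calls of histones, most of which lie on the short arm of chromosome 6 (adjusted p = 0.0512), and p53 targets (adjusted p = 0.0795) were lost with the preset correlation as well, with medians of the remaining members at -0.34 and -0.17. The pluripotency list then had under 5 members left and was not tested, so 11 of the 14 lists were called without these chromosomes. The p53 targets also lost theirs without control replicate 2 (adjusted p = 0.0709, median -0.10) and without PRMT1 knockdown replicate 1 (adjusted p = 0.0531, median -0.21).

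Chaperone, ribosome assembly and sterol genes were higher in the knockout. Of 16 cytosolic heat shock genes, 13 were higher and 1 lower (14 and 1 adjusted over the list alone; median 0.36), including HSPA8 (0.91 ± 0.09), DNAJA1 (0.77 ± 0.08) and HSPH1 (0.66 ± 0.08). Of 36 genes of ribosome biogenesis and MYC targets, 17 were higher and 2 lower (22 and 2 adjusted over the list alone; median 0.29). UTP20 (0.98 ± 0.10) and NOP16 (0.76 ± 0.10) rose, while MYC itself, on chromosome 8 at 128 Mb, fell by 0.70 ± 0.08. Of 24 cholesterol synthesis and uptake genes, 7 were higher and 1 lower (12 and 2 adjusted over the list alone; median 0.24), with ACAT2, on chromosome 6 at 159.8 Mb, higher (0.71 ± 0.09) and INSIG1 lower (-0.50 ± 0.09). Of 22 endoplasmic reticulum chaperones, 8 were higher and 3 lower (9 and 3 adjusted over the list alone; median 0.19): HYOU1 rose (0.50 ± 0.08), and DERL1, on chromosome 8 at 123 Mb, fell by 0.50 ± 0.09. By camera, adjusted p was 1.2e-10, 2.7e-07, 5.6e-04 and 0.00655 in that order. No call held: adjusted p = 0.408 with an estimated correlation for the heat shock, ribosome biogenesis and cholesterol lists, and adjusted p = 0.691 with an estimated correlation for endoplasmic reticulum chaperones. The other 31 of 45 lists were not called in the knockout (lowest adjusted p = 0.0758). Of 17 integrins, 7 were lower and 2 higher (8 and 2 adjusted over the list alone), ITGA4 falling by 2.32 ± 0.20, and of 37 HOX genes 4 were higher and 0 lower (2 higher adjusted over the list alone).

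Whole stretches of chromosomes were lower in the knockout, among genes with an average log2 CPM above 2, to which the counts and medians here refer. On chromosome 8 from 50 Mb to the end, the 252 such genes had a median log2 change of -0.45, with 157 called lower and 1 higher, against -0.02 for 142 genes from 0 to 50 Mb. On chromosome 6 from 70 to 170 Mb, the median of 273 genes was -0.30, with 133 lower and 9 higher, against 0.02 for 328 genes from 0 to 60 Mb. On chromosome 11 from 40 to 50 Mb, 31 of 42 genes were lower and 0 higher (median -0.50). In the PRMT1 knockdown the medians of these stretches were -0.09, 0.03 and -0.07. These medians are values with no test.

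**Figure D2:**
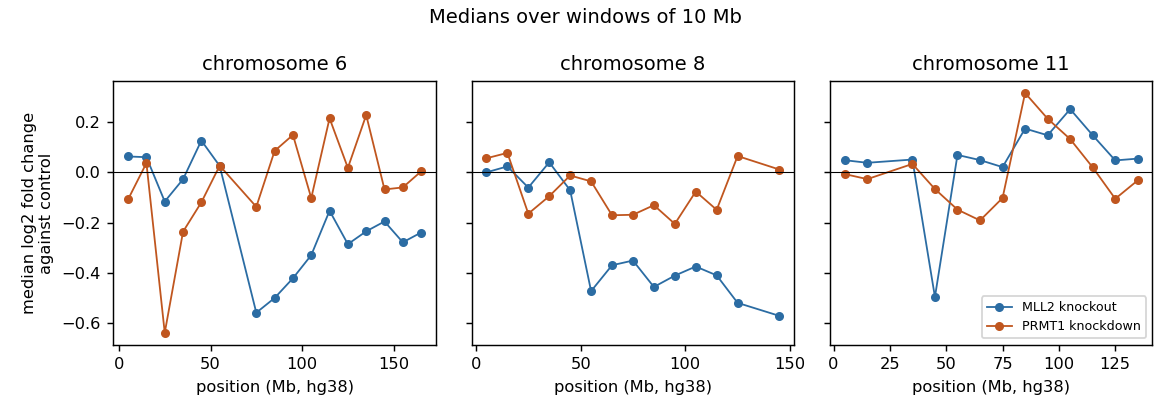
Median log2 fold change in windows of 10 Mb along chromosomes 6, 8 and 11, for each depletion against control. These chromosomes were picked because they hold the lower stretches. The 9 windows of chromosome 8 from 50 Mb lay at -0.35 or lower in the knockout.

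The PRMT1 knockdown changed more genes than the knockout. PCK1, a cytosolic enzyme of glucose synthesis, was at least 18.1-fold lower than in the control libraries and the homeobox gene MEOX1 at least 11.1-fold lower. The receptor kinase gene ROS1, on chromosome 6 at 117 Mb, was at least 14.8-fold higher. EMILIN2, a matrix glycoprotein gene on chromosome 18 (2847006 to 2916003), rose by 4.26 ± 0.12 (19.1-fold, adjusted p = 5.5e-16). Of 17575 genes, 8338 were called, 3899 higher and 4439 lower, and at a change of at least 2-fold 1066 were higher and 1790 lower. With the GC and length correction, which also moves the scaling between libraries, the balance turned, to 4657 higher and 4052 lower. MYC, on chromosome 8 at 128 Mb, fell by 1.69 ± 0.09, the cyclin gene CCND1 fell by 2.50 ± 0.16, and the secreted guidance gene SLIT2 rose by 1.98 ± 0.10.

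Short transcripts were lower and long ones higher in the knockdown libraries. The medians here are of 11490 genes with a GC value and an average log2 CPM above 2. The median log2 change was -0.45 for genes with under 1000 nt of exons and 0.16 for those over 8000 nt. Between the 2 knockdown libraries, replicate 2 minus replicate 1, the medians of those classes were -0.22 and 0.09. These values stand beside each group below whose genes are short, such as the histones and ribosomal proteins, or long, such as protocadherins, collagens and the KMT2 genes. For the lists called in the knockdown, against control or against the knockout, the median after a correction of the counts for GC content and length is given as well.

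**Figure D3:**
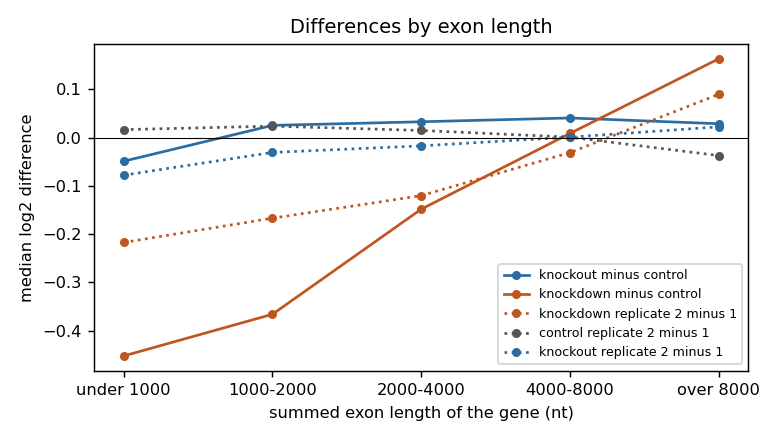
Median log2 difference by summed exon length, for each depletion against control and between the libraries of each group. In the knockdown the medians ran from -0.45 to 0.16.

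Replication-dependent histones, whose messages lack a poly(A) tail and rise in S phase, were lower in the knockdown in 39 of 46 cases and higher in 0 (39 lower adjusted over the list alone; median -1.20, and -1.20 with the gene at 0 counts set to its bound). H2BC13 (-1.87 ± 0.09), H3C10 (-1.75 ± 0.08) and H1-3 (-1.70 ± 0.09) led them. After the GC and length correction 35 were lower (median -0.86). Amino acid response genes were lower again, 34 of 38 with 0 higher (34 lower adjusted over the list alone; median -1.15, corrected -1.05): PCK2 (-3.93 ± 0.12), DDIT4 (-2.77 ± 0.09) and PHGDH, which opens serine synthesis (-2.07 ± 0.08). Of 78 cytosolic ribosomal proteins, 72 were lower and 2 higher (73 and 2 adjusted over the list alone; median -0.54), with RPL13A (-1.34 ± 0.09) and RPL3 (-1.15 ± 0.08), and 59 were lower after the correction (median -0.36). Of 32 hypoxia and glycolysis genes, 26 were lower and 2 higher (26 and 2 adjusted over the list alone; median -0.84, corrected -0.68), with PFKP (-1.82 ± 0.09) and the angiogenic factor VEGFA (-1.73 ± 0.10). Of 24 cholesterol genes, 15 were lower and 2 higher (15 and 2 adjusted over the list alone; median -0.37), or 12 and 2 after the correction (median -0.26), with INSIG1 (-2.04 ± 0.09) and HMGCS1 (-1.14 ± 0.09). Of 43 nuclear-encoded respiratory chain genes, 25 were lower and 1 higher (25 and 1 adjusted over the list alone; median -0.33), or 18 and 7 after the correction (median -0.12), with COX5B (-1.63 ± 0.10). In camera's test the adjusted p was 5.2e-40, 8.3e-39, 4.2e-18, 3.5e-13, 1.3e-04 and 6.1e-04 in that order. These calls did not hold: adjusted p = 0.387 with an estimated correlation for histones, 0.382 for the amino acid response, hypoxia and cholesterol lists, 0.579 for ribosomal proteins and 0.670 for the respiratory chain.

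Matrix genes were lower in the knockdown as well, in lists that are not independent evidence of a direction. Of 29 collagens, 19 were lower and 1 higher (21 and 2 adjusted over the list alone; median -1.11, corrected -1.06), with COL14A1 (-1.90 ± 0.13) and COL6A1 (-1.66 ± 0.12). Of 38 matrix remodelling genes, 22 were lower and 3 higher (22 and 3 adjusted over the list alone; median -0.79, corrected -0.70), with the prolyl hydroxylase P4HA1 (-1.35 ± 0.10) and the inhibitor TIMP3 (-1.32 ± 0.12). Of 42 laminins and matrix glycoproteins, 18 were lower and 5 higher (19 and 5 adjusted over the list alone; median -0.70, corrected -0.58): FN1 (-1.68 ± 0.09) and LAMA4 (-1.39 ± 0.10) fell while EMILIN2 rose. Of 21 neuronal genes, 7 were lower and 2 higher (7 and 2 adjusted over the list alone; median -0.27, and -0.27 with the gene at 0 counts set to its bound, corrected -0.32), with the neurofilament gene NEFL (-2.67 ± 0.09) and SYP, synaptophysin (-1.66 ± 0.16). Of 9 protein arginine methyltransferases, PRMT1 itself counted, 5 were lower and 1 higher (5 and 1 adjusted over the list alone; median -0.26, corrected -0.19). Without PRMT1, which the hairpin targets, 4 of 8 were lower and 1 higher (4 and 1 adjusted over the list alone; median -0.16), with falls of PRMT9 (-0.51 ± 0.12) and PRMT3 (-0.37 ± 0.09), and the list was not called (adjusted p = 0.685). With camera, the adjusted p was 1.1e-05, 4.1e-04, 0.0234, 0.0149 and 0.0114 in that order. None of them held: adjusted p = 0.414 with an estimated correlation for collagens and laminins, 0.382 for remodelling genes, 0.387 for neuronal genes and 0.579 for methyltransferases. The neuronal list also lost its call without chromosomes 6 and 8 (adjusted p = 0.383, median of the remaining members -0.26), without PRMT1 knockdown replicate 1 (0.0896, median -0.32) or without replicate 2 (0.0782, median -0.20), and the methyltransferases, PRMT1 counted, without the same libraries (0.0619 and 0.137, medians -0.25 and -0.24).

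Subunits of KMT2 histone methyltransferase complexes were mostly higher in the knockdown: 11 of 18 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.64, corrected 0.55). KMT2C was 2.57-fold higher and KDM6A rose (0.90 ± 0.09), while PSIP1 (-0.97 ± 0.09) and PAGR1 (-0.93 ± 0.10) fell. The list's median was 0.42 in knockdown library 1 and 0.79 in library 2. Of 16 non-clustered protocadherins and FAT cadherins, which are adhesion genes and not independent evidence, 7 were higher and 0 lower (7 higher adjusted over the list alone; median 0.31), with PCDH17 (1.38 ± 0.17) and FAT1 (0.94 ± 0.08). Their corrected median was 0.15, and the corrected counts gave no call (adjusted p = 0.155). Of 18 snoRNA host genes, whose introns carry small nucleolar RNAs, 10 were higher and 0 lower (12 and 1 adjusted over the list alone; median 0.34, corrected 0.37), with SNHG12 (0.75 ± 0.10) and SNHG20 (0.85 ± 0.14). The camera test gave adjusted p = 0.0104 for KMT2 subunits, 0.0146 for protocadherins and 0.0149 for snoRNA hosts. All were lost: adjusted p = 0.495 with an estimated correlation for KMT2 subunits, 0.579 for protocadherins and 0.598 for snoRNA hosts, whose call was also lost without PRMT1 knockdown replicate 1 (adjusted p = 0.0610, median 0.23). The other 31 of 45 lists were not called in the knockdown (lowest adjusted p = 0.0588, for cytosolic heat shock genes, 8 of 16 higher and 2 lower, with 9 and 2 adjusted over the list alone).

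**Figure D4:**
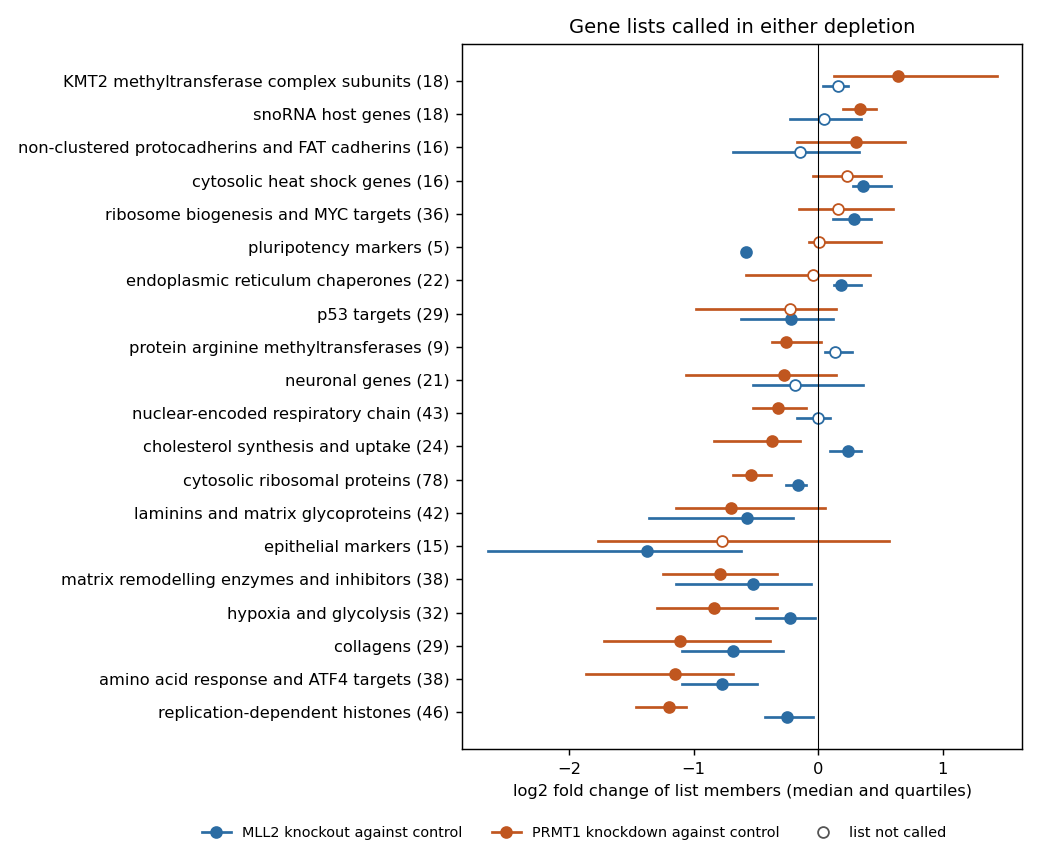
Median and quartiles of log2 fold change for each list called in either depletion, with the number of measured members. Cholesterol genes lay at 0.24 in the knockout and -0.37 in the knockdown.

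The knockdown and the knockout were also compared with each other directly, without the control libraries in the contrast. PKP3 was at least 11.9-fold higher in the knockdown than in the knockout. IGFBP5, a binder of insulin-like growth factors, was lower (-4.14 ± 0.16), and EMILIN2 was higher (4.57 ± 0.13). Of 24 cholesterol genes, 21 were lower in the knockdown and 0 higher (21 lower adjusted over the list alone; median -0.63, corrected -0.51), led by INSIG1 (-1.53 ± 0.09), HMGCS1 (-1.36 ± 0.09) and TM7SF2 (-1.81 ± 0.15). Histones were lower in 38 of 46 and higher in 1 (38 and 1 adjusted over the list alone; median -0.90, and -0.90 with genes at 0 counts set to their bounds, corrected -0.64), ribosomal proteins lower in 55 of 78 and higher in 3 (58 and 3 adjusted over the list alone; median -0.33), or 41 and 9 after the correction (median -0.22). Amino acid response genes were lower in 24 of 38 and higher in 4 (25 and 4 adjusted over the list alone; median -0.55, corrected -0.32), with PHGDH (-1.21 ± 0.08) and SHMT2, a serine hydroxymethyltransferase (-0.98 ± 0.09). Hypoxia genes were lower in 20 of 32 and higher in 4 (23 and 4 adjusted over the list alone; median -0.47, corrected -0.48): TPI1 fell (-1.15 ± 0.09) and ADM, adrenomedullin, rose (1.70 ± 0.13). Arginine methyltransferases, PRMT1 itself counted, were lower in 6 of 9 and higher in 0 (6 lower adjusted over the list alone; median -0.39, corrected -0.45). Without PRMT1 5 of 8 were lower (5 adjusted over the list alone; median -0.30) and the list was not called (adjusted p = 0.126). Camera's adjusted p was 6.7e-13 for cholesterol genes, 3.3e-33 for histones, 7.0e-10 for ribosomal proteins, 2.5e-08 for the amino acid response, 1.9e-06 for hypoxia and 9.2e-06 for methyltransferases. No list held its call: adjusted p = 0.344 with an estimated correlation for cholesterol genes, 0.628 for ribosomal proteins and 0.567 for the rest. In all, 7154 genes were called, 3401 higher and 3753 lower, or 4005 higher and 3572 lower with the GC and length correction.

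Further lists differed between the depletions, most of them by small medians. Respiratory chain genes were lower in 22 of 43 and higher in 3 (23 and 3 adjusted over the list alone; median -0.27), or 17 and 7 after the correction (median -0.12), S phase genes lower in 16 of 35 and higher in 4 (17 and 4 adjusted over the list alone; median -0.20, corrected -0.07), and mitosis genes lower in 16 of 35 and higher in 3 (16 and 3 adjusted over the list alone; median -0.27, corrected -0.09). COX5B (-1.40 ± 0.10), the replication licensing gene CDC6 (-0.94 ± 0.08) and the kinesin KIF23 (-1.19 ± 0.08) were among them. Ribosome biogenesis genes were lower in 16 of 36 and higher in 7 (17 and 7 adjusted over the list alone; median -0.17, corrected -0.03), and endoplasmic reticulum chaperones lower in 11 of 22 and higher in 5 (12 and 5 adjusted over the list alone; median -0.27, corrected -0.23), with PDIA4 (-1.04 ± 0.08). Fatty acid synthesis genes were lower in 7 of 14 and higher in 4 (7 and 4 adjusted over the list alone; median -0.18, corrected -0.17), with the elongase ELOVL6 (-1.84 ± 0.13) and the desaturase FADS1 (-1.16 ± 0.09) lower and ME1, on chromosome 6 at 83.2 Mb, higher (1.48 ± 0.12). Protocadherins and FAT cadherins were higher in 8 of 16 and lower in 0 (8 higher adjusted over the list alone; median 0.46), with PCDH10 (1.24 ± 0.11), and corrected counts gave 4 higher and 2 lower (median 0.24). Against all other genes, camera's adjusted p was 9.5e-04 for the respiratory chain, 0.0115 for S phase and protocadherins, 0.0299 for mitosis, 0.0378 for ribosome biogenesis, 0.0484 for chaperones and 0.0292 for fatty acids. Each call was lost: adjusted p = 0.567 with an estimated correlation for S phase, protocadherins and fatty acids, and 0.628 for the others. After the GC and length correction, fatty acid synthesis was the single list of these 7 still called, and its call was lost without PRMT1 knockdown replicate 1 (adjusted p = 0.128, median -0.20). Mitosis was not called without PRMT1 knockdown replicate 2 (0.106, median -0.21), and ribosome biogenesis without MLL2 knockout replicate 1 (0.0638, median -0.18) or PRMT1 knockdown replicate 2 (0.0524, median -0.10). Chaperones were not called without those libraries (0.0977 and 0.0569, medians -0.25 and -0.22), with size factors by relative log expression (0.0560, median -0.26), or with PRMT1 left out of the methyltransferase list, which changes the adjustment over lists (0.0525). The other 32 of 45 lists were not called with the uncorrected counts (lowest adjusted p = 0.0657).

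Many genes moved the same way in both depletions. SLC7A3 was lower in the knockdown too (-3.04 ± 0.26), as was MGAT3, a glycosyltransferase gene (-3.22 ± 0.22 in the knockout, -3.13 ± 0.21 in the knockdown). The giant muscle protein gene NEB (1.72 ± 0.25 and 1.83 ± 0.25) and TMEFF2 (3.33 ± 0.68 and 2.82 ± 0.69) were higher in both. In all, 1109 genes were higher in both and 1307 lower in both, where independent lists of these sizes would share 403 and 536. The balance turned with DESeq2 (1110 higher, 959 lower), relative log expression (1293 and 1223) and the GC and length correction (1595 and 1296). The correlation of the fold changes was 0.513. Both comparisons use the same 2 control libraries, so part of any excess may come from them. In 50 simulated pairs of unchanged groups with shared controls, all libraries, the controls too, were drawn from the control means. The mean correlation was 0.502 and the highest 0.530, and the mean covariance of fold changes was 0.104, against 0.485 observed. Such draws carry counting noise and replicate spread only. With a separate control library for each depletion, 379 genes were higher and 625 lower in both (independent lists would share 108 and 222; correlation 0.339) when control replicate 1 served the knockout. When control replicate 2 served it, 460 were higher and 667 lower (129 and 240 for independent lists; correlation 0.311). A state common to both control cultures would remain in these counts. The 2416 genes called the same way were 1328 without control replicate 1, 1138 without control replicate 2, 1465 without MLL2 knockout replicate 1 and 1438 without MLL2 knockout replicate 2. Another 278 genes were called in opposite directions, 150 higher in the knockout and 128 higher in the knockdown, fewer than independent lists of these sizes would share. All 278 were also called between the depletions, which opposite changes against the same control libraries made nearly certain.

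Markers of other cell types differed between groups in part. Pluripotency markers summed to 238 and 235 CPM in the control libraries, 162.9 and 162.9 CPM in the knockout and 262 and 251 CPM in the knockdown, with LIN28B the largest. Fibroblast markers summed to 30.1 and 34.03 CPM in the control libraries, 22.95 and 23.9 CPM in the knockout and 28.1 and 29.3 CPM in the knockdown, with TWIST1 the largest. Blood cell markers summed to 6.59 CPM or less in every library, and hepatocyte markers to 1.46 CPM or less. Keratinocyte markers summed to 225 and 210 CPM in the control libraries, 217 and 214 CPM in the knockout and 313 and 294 CPM in the knockdown, nearly all from the desmosomal cadherin DSC3. Long noncoding RNAs took 1.358% and 1.35% of counts in the control libraries, 1.21% and 1.25% in the knockout, and 1.58% and 1.83% in the knockdown. These sums carry no test.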

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

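Both results here were picked out after the values were seen, by a fixed rule for differences between the groups. The first is the cholesterol synthesis and uptake list, which was called higher in the MLL2 knockout (median log2 change 0.24) and lower in the PRMT1 knockdown (median -0.37). Few single members were called opposite ways: 7 of 24 were called higher in the knockout and 1 lower, 15 lower in the knockdown and 2 higher, and 2 members were called in opposite directions. With an estimated correlation both list calls were lost (adjusted p = 0.408 and 0.382). Between the knockdown and the knockout its median was -0.63, with 21 of 24 genes called lower and 0 higher in that direct test. Among the lower members were HMGCS1 (-1.36 ± 0.09), TM7SF2 (-1.81 ± 0.15) and FDPS (-0.96 ± 0.08). The list's call between the depletions was lost in the same way (adjusted p = 0.344). No explanation for this difference was tested.

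The second result is a set of 278 genes that were called in opposite directions in the MLL2 knockout and the PRMT1 knockdown, each against control, and were also called between them. Independent lists of these sizes would share more opposite genes than this, so the set is no excess of opposite changes. Opposite changes against the same control libraries made the call between the depletions nearly certain. Of these, 150 were higher in the knockout and lower in the knockdown, and 128 were lower in the knockout and higher in the knockdown. TERT, the telomerase reverse transcriptase gene, fell in the knockout (-2.08 ± 0.32) and rose in the knockdown (0.95 ± 0.26). LRP2, megalin, a receptor of kidney tubules, did likewise (-1.04 ± 0.13 and 0.80 ± 0.12). INSIG1 was lower in both depletions and is not among them. No explanation for this set was tested either.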

How the results depend on the processing

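The GC and length correction and the fits without chromosomes 6 and 8 or without PRMT1 in its list, and those with a separate control library for each depletion, were chosen after the results were seen. With an estimated correlation camera called 0 lists in the knockout, 0 in the knockdown and 0 between them, in place of 14, 14 and 13, and the cause was not tested. That correlation was estimated from 3 residual degrees of freedom, so a lost call does not show that a list was unchanged. The fry test called 14, 28 and 18 lists in these comparisons. With the GC and length correction 8 lists were called between the depletions, and the cause was not tested. Leaving out 1 library at a time, with the lone library of a group assumed to vary like the others, the calls in the knockout ran from 1908 (without control replicate 2) to 5492 (without PRMT1 knockdown replicate 2), the genes called the same way in both depletions from 1138 to 3127, and the correlation of the fold changes from 0.37 (without MLL2 knockout replicate 2) to 0.652 (without control replicate 1). With a separate control library for each depletion, 1004 and 1127 genes were called the same way (control replicate 1 or 2 for the knockout), with correlations of 0.339 and 0.311. The log2 change of KMT2B in the knockout ran from -0.0543 (without control replicate 1) to 0.10, with 0.02 for all libraries, and that of KMT2D from 0.00304 (without control replicate 2) to 0.40 (without control replicate 1), with 0.19 for all. Without PRMT1 in the methyltransferase list, 13 lists were called in the knockdown and 11 between the depletions. The calls of the knockdown (6416 to 8238) and between the depletions (5243 to 7333) stayed within 1.5 times the reported counts, and PRMT1 in the knockdown stayed between -3.17 and -3.03. Under relative log expression, DESeq2, the other filters, protein-coding genes alone and the fits of 2 groups, every count of calls stayed within 1.5 times the reported one. The balance of higher and lower calls did not keep its side: in the knockdown it was 3699 higher and 3683 lower with DESeq2 and 4084 and 4047 in the fit of the 2 groups, and between the depletions 3545 and 3498 with no count filter. The library numbers do not pair the groups (correlations of the differences 0.025, 0.044 and 0.082), and a term for the number gave 4512, 8710 and 7529 called genes, with every list reported as called and every single gene reported as changed still called.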

Other observations

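Genes outside the called lists also changed. In the knockdown the interferon-induced gene IFIT1 was lower (-1.73 ± 0.21), as were the Notch target HEY1 (-1.56 ± 0.08), which lies on chromosome 8 at 79.8 Mb, and the actin crosslinker FLNA (-1.14 ± 0.08). SMAD7, an inhibitor of TGF-beta signals, was higher (1.57 ± 0.11), and so was the calcium channel subunit CACNB4 (2.11 ± 0.15). In the knockout NOTCH3 was lower (-2.23 ± 0.29), while the guidance gene SEMA3C rose in both depletions (1.33 ± 0.11 and 1.56 ± 0.11). Their lists were not called in these comparisons, and the genes stand here as single values.

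The tests below were all chosen after the result was seen. The first pattern is the length trend of the knockdown libraries. If single libraries differ in RNA integrity or fragment length, the trend should also appear between libraries of the same group. The Spearman correlation of the log2 ratio of the 2 knockdown libraries with exon length was 0.374. For control and knockout it was -0.12 and 0.11. Such a difference could explain part of the trend. Carried by 1 library alone, the trend would set the knockdown libraries further apart than their group lay from control. Genes under 1000 nt lay at -0.45 against control and at -0.22 between the knockdown libraries, and those over 8000 nt at 0.16 and 0.09. Both libraries thus carried the trend, and a cause common to them was not tested. Genomic DNA among the reads was tested through olfactory receptor genes, which these cells hardly express: their read density would give 0.0819% of the counts of genes over 8000 nt, too little to lift them. For the histones, whose transcripts are short, the list median after correction was -0.86, so length and GC trends could explain part of the fall but not all of it. Other genes under 1000 nt, with an average log2 CPM above 2, went from -0.39 to 0.02 with the same correction. A lower rate of histone messages per cell, a biological reading, was not tested apart from this.

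The second pattern is the lower stretch of chromosome 8 in the knockout. A shift of the whole chromosome is contradicted by a highest window median of 0.0396. From 50 Mb on, 96.0% of the genes with an average log2 CPM above 2 lay below the median of all other such genes, with libraries at -0.46 and -0.44. The stretch was picked for its low windows, so this share restates the pattern and is no test of a lost copy. The corrected median of -0.46 speaks against GC and length trends, and the upper quartile, lower than elsewhere by a difference of -0.49, speaks against single regulated genes among unchanged neighbours. A copy number difference between cultures or clones stays open, and DNA was not measured. An effect of the knockout on chromatin over the stretch, the biological reading, cannot be told apart from it by these counts. Of 275 windows on other chromosomes, 5 lay below -0.3, all on chromosome 6 between 70 and 110 Mb or on chromosome 11 between 40 and 50 Mb.

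The third pattern is the lower amino acid response in both depletions, which share their control libraries. If the state of the control cultures alone made both falls, knockdown and knockout would not differ from each other. The list median between them was -0.55 (-0.32 after the GC and length correction), so the control state could not be the whole cause of both. This difference does not tell which depletion moved, so for either depletion taken alone the control state is not excluded. A single unusual control culture would set the control libraries apart, and their list medians differed by 0.0643. GC and length trends are contradicted by corrected medians, the smaller fall being -0.69. A state shared by both control cultures, such as medium or density, may still contribute to the fall in either depletion. A lower ATF4 response in depleted cells remains the biological reading, and these libraries cannot separate it from such a state.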
